A study of Mus musculus with 12 samples.

How the data were processed

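Splenic CD4 T cells, taken by flow sorting from female mice, were profiled on Illumina mouse expression arrays, 1 array per sample. The 12 samples fell into 3 groups of 4 by their labels: uninfected C57BL/6 mice, C57BL/6 mice infected with Plasmodium berghei ANKA, and infected mice of the B6.GzmB-/- strain, in which the granzyme B gene is inactivated. The animals were 8 to 10 weeks old, infected mice had received 100000 parasitised red cells into a vein, and spleens were taken 4 days later, per the labels' protocols. RNA with a 28S to 18S ratio of at least 1.7 was used, per the same protocols. The design text gives 4 mice per group, so each array is treated as 1 mouse and p-values measure the spread between mice.

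The deposited intensity table holds, per probe and array, a brightness on a linear scale that had not been normalized between arrays and from which background had not been subtracted, as its values show. The detection p-value deposited beside each intensity sets a probe against the negative controls of its array, per the file headers. GenomeStudio is named in the submitters' processing notes, with no version or settings given in the sources used here. The deposited value table was found, by comparison with the intensities, to hold the log2 intensity less the 75th percentile of its array and less the median of each probe over the 12 arrays. The largest departure from this was 0.000337, every column of 1 table matched a column of the other from the same group, and scale, centring and direction are thereby settled. The median of a value table column ranged from -0.112 to 0.158. The columns of the intensity table carry a group letter and an array name (N1 to N4 uninfected, B3 to B6 infected C57BL/6, G1, G3, G4 and G6 infected GzmB-/-), which are used here, and no replicate number of the labels.

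Background was corrected by normexp from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none there. Symbols were updated through the Entrez number in a RefSeq gene table of assembly GRCm38.p6 for 34807 probes, and 78 kept the platform's symbol. That table was used only for names, chromosomes and gene order, because the sources used here give no build or position for the probes. A probe was kept when its detection p was under 0.05 on at least 4 arrays. This left 16597 probes, 13922 of them with 1 gene, and the brightest probe stood for each of 9018 genes. Where a gene had more than 1 probe past the filter, as 3378 genes did, the span over its probes was recorded. Between 14783 and 16259 probes were detected per array, and the array median ran from 122.3 to 143.3. For arrays, the number of arrays limits the precision, and the median standard error of a difference was 0.151 on the log2 scale.

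All 12 arrays entered 1 limma fit (lmFit, contrasts, eBayes), and two-sided p-values were adjusted by Benjamini-Hochberg over the 9018 genes, with 0.05 as the threshold. Errors written as ± after a log2 difference are standard errors of that fit with n = 4 per group, and those after a mean are standard deviations. Where the probe used for a gene was not detected on any array of a group, the change is given as a bound, the mean of the brighter group over the lowest level of detected probes in the dimmer one, with the adjusted p of the fit. Such bounds apply to the background-corrected scale only. Before the data were examined, 32 gene lists holding 819 genes were written: interferon responses, T helper and regulatory programmes, cytotoxic genes, proliferation, naive state, activation, metabolism, ribosome, stress, apoptosis, T cell identity, and markers of other cells a spleen sort could hold. Lists with at least 5 tested genes, 30 of them covering 574 genes, were tested by camera with a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it.

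The rule for named genes, also set then, was Gzmb, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups of 4 do not overlap, without clone or locus names, up to 3 members of each list, and any called gene on the chromosome of Gzmb. In the third comparison, which called few genes, every called gene is named. The text gives a selection of the genes the rule yields, and says where a gene outside it was chosen later. Alternatives were no background correction, median scaling, the deposited value table, an offset of 50, a detection p under 0.01, detection on all 12 arrays, no filter, the mean of the probes, a trended robust eBayes, array weights, only the 8 arrays compared, a fold threshold of 2, other list tests and each array left out. A slide block was not run, since the sources used here give no slide, and 3 alternatives were added after seeing the data: a replicate block on the value table, leaving out arrays B3 and G3, and the monocyte and macrophage score as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

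The steps were tested on simulated data with the real means and spreads of the 9018 genes, where per comparison 67 genes were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For infected against uninfected C57BL/6 mice, 32.8% of genes changed by 0.5 on the log2 scale were recovered, 83.6% at 1 and 98.5% at 2, with 8 of 8818 unchanged genes called. For infected GzmB-/- against uninfected C57BL/6 mice the shares were 20.9%, 89.6% and 97%, with 1 unchanged gene called. Between the infected genotypes they were 29.9%, 89.6% and 100%, with 6 unchanged genes called. The real data called 3528 and 3460 genes in the comparisons with uninfected mice and 17 between the infected genotypes, unlike the simulated number of changed genes. As the adjusted threshold depends on that number, real recovery may be higher than given in the first 2 comparisons and lower between genotypes. In each comparison 3 of 3 lists shifted by 0.5 were called and 0 of 26 lists without shifted genes. The simulated genes varied independently of each other. The list result therefore does not cover lists whose genes move together, such as S phase genes, with an estimated correlation of 0.56 in the real data.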

Results

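The arrays measured messenger RNA of CD4 T cells from the spleens of 3 groups of 4 mice, with 9018 genes above background. Plasmodium berghei ANKA is a rodent malaria parasite used as a model of cerebral malaria, and granzyme B is a serine protease that cytotoxic lymphocytes release into target cells. The 3 comparisons ask what infection changed in CD4 T cells of C57BL/6 mice by day 4, how infected GzmB-/- mice differed from uninfected C57BL/6 mice, and whether the infected genotypes differed. The first principal component held 61.8% of the variance and parted the 4 uninfected arrays from the 8 infected ones. The second held 9.47% and ran within the infected arrays, from 27.81 for array B3 to -22.36 for array G3.

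**Figure D1:**
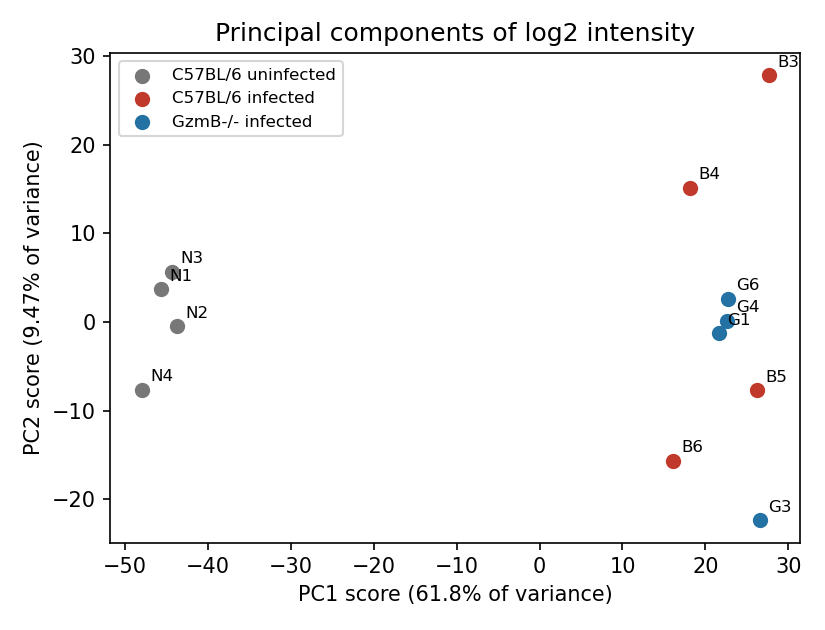
Scores of the 12 arrays on principal components 1 (61.8% of the variance) and 2 (9.47%), 1 point per array, coloured by group. Uninfected arrays lie at -43.74 or lower on component 1 and infected arrays at 16.04 or higher, while B3 and G3 lie at the ends of component 2.

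Gzmb itself was read first, since it is the targeted gene. Its 1 probe was detected on 0 of the 12 arrays, with a lowest detection p of 0.38462 and intensities from 86.8 to 131.7. The log2 level was 4.89 ± 0.13 (SD, n = 4) in uninfected C57BL/6, 4.86 ± 0.06 in infected C57BL/6 and 4.80 ± 0.14 in infected GzmB-/- mice. A transcript that no group showed above background leaves the genotype labels unchecked, and where the probe lies relative to the inactivated part is not given in the sources used here. Of the related granzymes, Gzmk was detected on 10 arrays and Gzmm on 12. In the granzyme and mast cell protease cluster that surrounds Gzmb, 15 genes had a probe and 0 passed the detection filter, so that list was not tested.

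Infection of C57BL/6 mice was accompanied by a very large rise of interferon-induced genes in splenic CD4 T cells. Ifitm3 and Ifitm1, membrane proteins that restrict virus entry, rose by 6.24 ± 0.21 and 6.00 ± 0.17 on the log2 scale (n = 4 per group), which for Ifitm3 is 75.8-fold. The chemokine gene Cxcl10 rose by 5.21 ± 0.21, the antiviral GTPase gene Mx2 by 4.95 ± 0.14, Ifit3 by 4.80 ± 0.16 and Irf7, a transcription factor of the interferon response, by 4.76 ± 0.18. Proliferation genes rose with them, among them Tk1, which encodes thymidine kinase, by 3.83 ± 0.31, and genes of the naive state fell. The falls were smaller than the rises: the largest by the rule were Pdlim4 at -2.53 ± 0.15, Sytl2 at -2.36 ± 0.15 and Dennd2c at -2.22 ± 0.17. The probes of Ifitm1 differed in size, running from 1.88 to 6.00.

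In all, 3528 of 9018 genes (39.1%) passed limma's adjusted threshold, 1647 higher and 1881 lower in infected mice, and 914 of them changed at least 2-fold (627 higher, 287 lower). At least 4-fold, 220 were higher and 9 lower. The groups of 4 did not overlap for 37.9% of the genes, against 2.86% by chance. The balance of higher and lower depends on scaling: with median scaling 902 were higher and 2841 lower, and the median of all genes then lay at -0.25 instead of -0.04. Other large rises outside the interferon lists were those of Tgm2, encoding tissue transglutaminase (4.77 ± 0.20), and Gadd45g, a stress-response gene (4.60 ± 0.15). Further falls were those of Arhgap29 (-2.14 ± 0.20), Scg5 (-2.13 ± 0.24), Tet1, which encodes an enzyme of DNA demethylation (-2.11 ± 0.23), and Qpct (-2.09 ± 0.19). Nme7 read -1.98 ± 0.11 on its brightest probe, but its probes ran from -1.98 to 1.15.

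Of 33 tested interferon-stimulated genes, 32 rose and 1, Ifi27, fell by 1.75 ± 0.14. The same 32 and 1 were found adjusted over the list alone, the list's median was 3.24 and camera gave an adjusted p of 1.05e-31, with adjusted p = 0.00959 with an estimated correlation. Of 28 interferon-gamma-inducible GTPases and antigen processing genes, 25 rose and 0 fell, also 25 adjusted over the list alone. The guanylate-binding protein genes Gbp5 (3.40 ± 0.21), Gbp2 (2.99 ± 0.11) and Gbp3 (2.83 ± 0.13) led it. Its median was 1.31, with a camera adjusted p of 1.26e-17 and adjusted p = 0.00239 with an estimated correlation. These 2 lists are the ones whose call held with an estimated correlation in this comparison.

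Cell division genes rose broadly. Of 31 S phase genes 28 rose, 0 fell and 3 were not called (28 adjusted over the list alone), with a median of 1.27 and a camera adjusted p of 1.56e-14, but adjusted p = 0.234 with an estimated correlation. The replication genes Mcm10 (3.62 ± 0.30) and Cdc6 (2.90 ± 0.21) were among them. Of 32 G2 and M phase genes 27 rose and 0 fell (28 and 1 adjusted over the list alone), with a median of 1.91 and a camera adjusted p of 9.4e-13, and adjusted p = 0.234 with an estimated correlation. Examples are Kif2c, a mitotic kinesin gene (3.15 ± 0.33), Birc5, the survivin gene (3.08 ± 0.22), and Cdca3 (2.96 ± 0.30).

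Genes of naive and quiescent T cells fell: 18 of 25 were lower, 0 higher and 7 not called, also 18 adjusted over the list alone. Dapl1 fell by 2.02 ± 0.22, Cd55, which encodes a complement regulator, by 1.94 ± 0.14 and Il6ra, the interleukin 6 receptor gene, by 1.57 ± 0.37. The median was -0.89 with a camera adjusted p of 9.48e-07, and adjusted p = 0.053 with an estimated correlation. Of 25 activation and checkpoint receptors 14 rose and 5 fell (14 and 7 adjusted over the list alone), with a camera adjusted p of 0.0123 and adjusted p = 0.106 with an estimated correlation. The inhibitory receptor genes Lag3 (3.22 ± 0.40) and Ctla4 (2.54 ± 0.15) and the PD-L1 gene Cd274 (2.52 ± 0.09) were its largest rises. Of 17 activation-induced transcription factors 9 rose and 2 fell, the same adjusted over the list alone, among them Bcl3 (2.83 ± 0.25), Irf8 (2.51 ± 0.16) and Nfkb2 (1.89 ± 0.14). Its camera adjusted p was 0.00699, and adjusted p = 0.102 with an estimated correlation.

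T helper genes moved mainly upward. Of 25 Th1 genes 13 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 0.44, a camera adjusted p of 0.00534 and adjusted p = 0.242 with an estimated correlation. The chemokine gene Ccl4 rose by 2.93 ± 0.47 and the interferon gamma gene Ifng by 2.85 ± 0.26. Havcr2, which encodes the inhibitory receptor Tim-3 and was not detected in uninfected mice, was at least 3.86-fold higher. Of 19 regulatory T cell genes 11 rose and 0 fell, the same adjusted over the list alone, with a camera adjusted p of 1.21e-05 and adjusted p = 0.18 with an estimated correlation. Il10, which encodes a suppressive cytokine, was at least 6.36-fold higher and Tnfrsf4, the OX40 gene, rose by 2.18 ± 0.16. The Foxp3 probes differed, running from -0.26 to 1.18. Of 14 follicular helper genes 6 rose and 1 fell, the same adjusted over the list alone, among them Asb2 (1.56 ± 0.20), the chemokine receptor gene Cxcr5 (1.38 ± 0.20) and Bcl6 (1.09 ± 0.15). Its camera adjusted p was 0.0399, and adjusted p = 0.242 with an estimated correlation, and the call ended without array N4 (adjusted p 0.0668) or B3 (0.0828), and with the monocyte score as covariate (0.0801).

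Some markers of other cells, in the MHC class II and monocyte lists above all, rose in the same arrays. Of 13 genes for MHC class II and antigen presentation 11 rose and 1 fell, the same adjusted over the list alone, with a median of 1.51, a camera adjusted p of 0.000171 and adjusted p = 0.325 with an estimated correlation. Cd40 was at least 4.22-fold higher on its brightest probe (probes from 0.50 to 2.94 on the log2 scale), the invariant chain gene Cd74 by 2.15 ± 0.28 and H2-DMb1 by 2.03 ± 0.38. Of 22 monocyte and macrophage markers 10 rose and 3 fell (11 and 3 adjusted over the list alone), with a camera adjusted p of 0.0302 and adjusted p = 0.565 with an estimated correlation. Mpeg1 rose by 3.47 ± 0.27, the Fc receptor chain gene Fcer1g by 2.72 ± 0.45 and Spic by 2.47 ± 0.49. That call ended without array B3 (median 0.46, adjusted p 0.139), N2 (0.079) or N3 (0.0506). The neutrophil gene S100a8 was at least 8.75-fold higher (at least 4.39-fold without B3), reaching 11.98 on array B3 and 7.786 to 8.198 on the other infected C57BL/6 arrays. Lyz2 ranged from 6.935 on B4 to 10.53 on B3, and Cd4 read 9.411 on B3 against 10.4 to 10.77 on the other 3. With genes undetected in uninfected mice set to their bounds, the median of the monocyte list was 0.58 instead of 0.80, and those of interferon-stimulated, S phase, G2 and M phase and Th1 genes were 3.20, 1.25, 1.86 and 0.42.

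**Figure D2:**
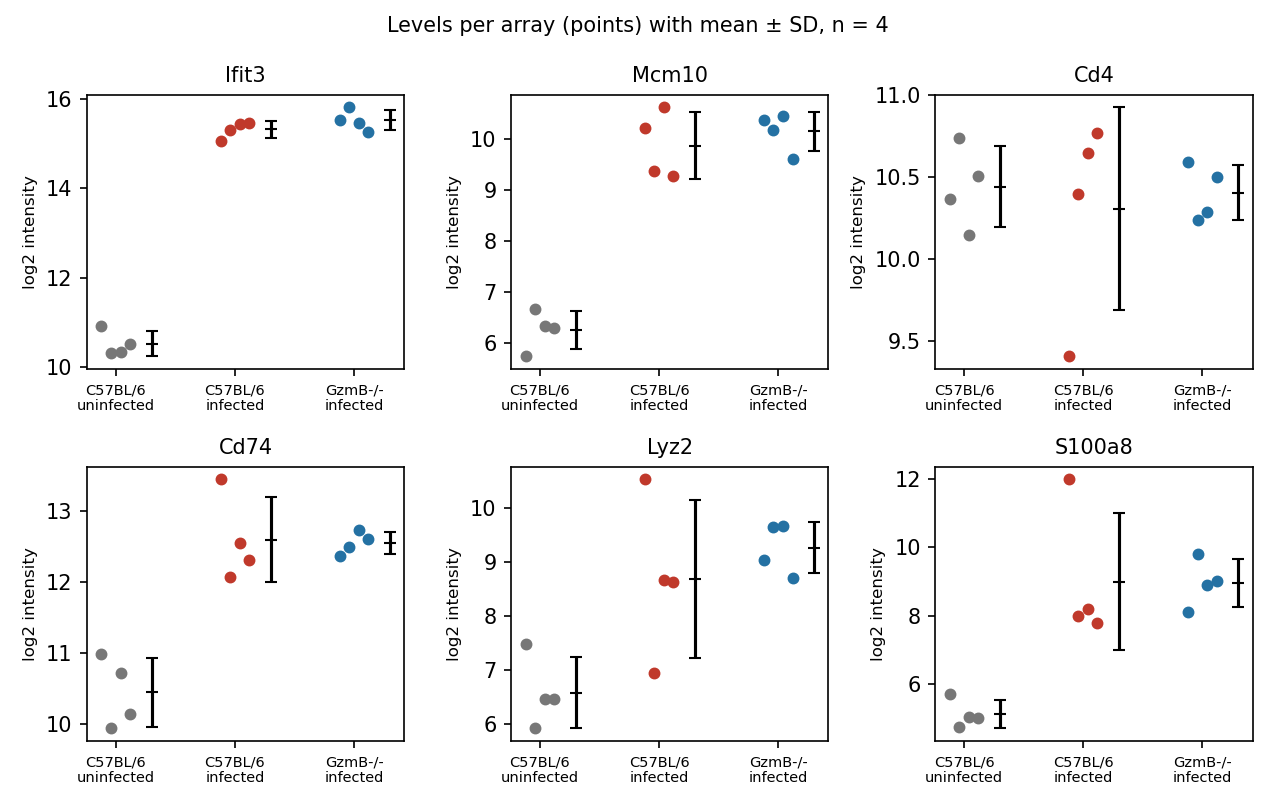
Log2 intensity of Ifit3, Mcm10, Cd4, Cd74, Lyz2 and S100a8, with points for single arrays and bars for mean ± SD (n = 4) in each group. Ifit3 and Mcm10 part infected from uninfected arrays, while S100a8 runs from 7.786 to 11.98 among infected C57BL/6 arrays.

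Ribosome biogenesis genes fell in part, with 1 of 23 higher and 9 lower, the same adjusted over the list alone, among them Polr1b, an RNA polymerase I subunit gene (-0.97 ± 0.14). Its camera adjusted p was 0.0489, with adjusted p = 0.423 with an estimated correlation, and the call ended without array N3 (0.0506), N4 (0.0893), B4 (0.0933), B5 (0.088) or G6 (0.0507). The other lists were not called by camera. Among them, 11 of 24 apoptosis genes were higher and 3 lower, with an adjusted p of 0.0765, Casp4, an inflammatory caspase gene, at 2.42 ± 0.16 and Bcl2, a survival gene, at -1.09 ± 0.14. Of 18 cholesterol and fatty acid synthesis genes 2 were higher and 7 lower, with an adjusted p of 0.098, Sqle, the squalene epoxidase gene, at -1.51 ± 0.24 and Elovl6 at 1.69 ± 0.18. Of 21 genes of the unfolded protein response 6 were higher and 2 lower, with an adjusted p of 0.306, a median of -0.00708 but a mean of 0.24, Asns at 2.37 ± 0.38 and Ddit3 at 1.74 ± 0.17. Of 23 immediate early and heat shock genes 6 were higher and 3 lower, with an adjusted p of 0.144 and Jun at 1.86 ± 0.19. Of 16 cytotoxic effector genes 8 were higher and 4 lower, with an adjusted p of 0.17, Gzmk at 1.92 ± 0.42 with overlapping groups.

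Of 16 glycolysis genes 5 were higher and 3 lower (adjusted p 0.106), and of 49 oxidative phosphorylation genes 8 were higher and 0 lower (adjusted p 0.279). Among 51 cytosolic ribosomal protein genes 0 were higher and 6 lower (adjusted p 0.348), and among 8 Th2 and Th17 genes 1 was higher (adjusted p 0.306). Among 19 T cell identity genes 1 was higher and 6 lower (adjusted p 0.11), with the costimulatory receptor gene Cd28 at -1.39 ± 0.16 and Themis at -1.32 ± 0.13. For other cells, 3 of 10 B cell markers were higher and 1 lower (adjusted p 0.11), 3 of 7 plasma cell markers were higher (0.0765), with Irf4 at 1.61 ± 0.17, and 3 of 5 neutrophil markers were higher (0.11). Of 9 NK cell markers 4 were higher and 2 lower (0.101), with Tyrobp at 2.06 ± 0.42 and Klrd1 at -1.13 ± 0.20. Tyrobp and Fcer1g are also in the monocyte list, and without them the mean change of the other 7 NK markers was 0.213, against 0.70 for all 9. Of 6 dendritic cell markers 1 was higher and 1 lower (0.472), of 8 erythroid markers 1 was higher (0.472), and of 5 CD8 and gamma-delta T cell markers 1 was higher and 2 lower (0.638). The last list had a median of 0.20 but a mean of -0.30. Without array B4 the plasma cell (median 0.39, adjusted p 0.0362) and NK cell lists (0.95, 0.0418) were called. Of the platelet markers, 3 were tested and 1, Tubb1, was at least 1.11-fold lower, with an adjusted p of 0.00325 and without passing in the deposited value table (-0.15, adjusted p 0.279).

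In infected GzmB-/- mice, set against uninfected C57BL/6 mice, the interferon genes again held the largest rises. Ifitm3 was higher by 6.10 ± 0.21 (n = 4 per group), Ifitm1 by 6.05 ± 0.17, Cxcl10 by 5.55 ± 0.21 and Ifit3 by 4.99 ± 0.16, and the interferon-gamma-induced chemokine gene Cxcl9 was at least 15.9-fold higher. Among infected C57BL/6 arrays Cxcl9 was highest on B3 (11.05) and lowest on B4 (8.249). So was Lyz2 (10.53 and 6.935), read above with the markers of other cells. T cells and other cells cannot be told apart as the source of Cxcl9. Ube2l6, a gene of ISG15 conjugation, rose by 4.53 ± 0.28 and Plac8 by 4.50 ± 0.16. The largest fall was that of Supt16, a subunit gene of the FACT histone chaperone, at -4.09 ± 0.17, although its other probe read 1.11. Pdlim4 (-2.83 ± 0.15), Scg5 (-2.57 ± 0.24), the T cell transcription regulator gene Zmiz1 (-2.39 ± 0.51) and Sox4 (-2.38 ± 0.45) followed. There was no uninfected GzmB-/- group, so this comparison holds genotype and infection together.

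Here 3460 genes (38.4%) passed limma's adjusted threshold, 1482 higher and 1978 lower, and 898 changed at least 2-fold, 613 higher and 285 lower. With median scaling the split was 881 higher and 2864 lower, with the median of all genes at -0.27 instead of -0.06. The groups did not overlap for 39.1% of the genes, against 2.86% by chance. Of 33 interferon-stimulated genes 32 rose and 1 fell, the same adjusted over the list alone, with a median of 3.35, a camera adjusted p of 9.82e-34 and adjusted p = 0.00771 with an estimated correlation. Of 28 interferon-gamma-inducible genes 25 rose (26 adjusted over the list alone), with a camera adjusted p of 5.88e-19 and adjusted p = 0.00179 with an estimated correlation. Gbp5 rose by 3.46 ± 0.21 and Gbp2 by 3.10 ± 0.11.

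Of 31 S phase genes 28 rose (29 adjusted over the list alone), led by Mcm10 at 3.90 ± 0.30, with a camera adjusted p of 2.15e-17 and adjusted p = 0.154 with an estimated correlation. Of 32 G2 and M phase genes 26 rose (27 adjusted over the list alone), led by Birc5 at 3.55 ± 0.22, with a camera adjusted p of 6.76e-15 and adjusted p = 0.155 with an estimated correlation. Of 25 naive genes 17 fell, the same adjusted over the list alone, with Cd55 at -1.77 ± 0.14, a camera adjusted p of 2.51e-06 and adjusted p = 0.0474 with an estimated correlation. Among 25 activation and checkpoint receptors 14 rose and 6 fell (14 and 7 adjusted over the list alone), with Ctla4 at 2.63 ± 0.15, a camera adjusted p of 0.00213 and adjusted p = 0.0474 with an estimated correlation. Among 17 activation-induced transcription factors 9 rose and 3 fell, the same adjusted over the list alone, with Irf8 at 2.23 ± 0.16, a camera adjusted p of 0.00197 and adjusted p = 0.0474 with an estimated correlation. The lists whose call held with an estimated correlation in this comparison are the 2 interferon lists and these last 3, on naive genes, activation receptors and activation-induced transcription factors.

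Th1 genes rose in 15 of 25 cases and fell in 1 (15 and 2 adjusted over the list alone), with Ifng at 2.81 ± 0.26, a camera adjusted p of 0.000161 and adjusted p = 0.143 with an estimated correlation. Of 14 follicular helper genes 9 rose and 0 fell, the same adjusted over the list alone, including the cytokine gene Il21 at 2.27 ± 0.55, with a camera adjusted p of 0.00213 and adjusted p = 0.13 with an estimated correlation. Of 19 regulatory T cell genes 11 rose and 1 fell, the same adjusted over the list alone, Il10 being at least 9.83-fold higher, with a camera adjusted p of 0.000161 and adjusted p = 0.18 with an estimated correlation. Some markers of other cells rose here too. Of 13 MHC class II genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Cd74 at 2.11 ± 0.28, a camera adjusted p of 0.000161 and adjusted p = 0.281 with an estimated correlation. Of 22 monocyte and macrophage markers 10 rose and 1 fell (10 and 2 adjusted over the list alone), with Mpeg1 at 3.40 ± 0.27, a camera adjusted p of 0.00781 and adjusted p = 0.566 with an estimated correlation. S100a8 was at least 8.5-fold higher and read 8.092 to 9.809 on these arrays.

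Of 9 NK cell markers 6 rose and 2 fell, the same adjusted over the list alone, with a camera adjusted p of 0.0471 and adjusted p = 0.229 with an estimated correlation, and the call ended without array N2 (0.0594), B5 (0.0504), B6 (0.0524) or G3 (0.107). Without Fcer1g and Tyrobp, which the monocyte list also holds, the mean change of the other 7 NK markers was 0.305, against 0.79 for all 9, and 0.18 ± 0.15 with the monocyte score as covariate, where the call of the whole list ended (adjusted p 0.0654). Of 7 plasma cell markers 3 rose, the same adjusted over the list alone, with Mzb1 at 1.95 ± 0.49, a camera adjusted p of 0.04996 and adjusted p = 0.313 with an estimated correlation, and the call ended without array N1 (0.0572), N2 (0.073), B5 (0.0512), B6 (0.0546), G3 (0.0827) or G6 (0.0605). With the monocyte score as covariate the plasma cell call ended too (adjusted p 0.214), the mean falling from 0.69 to 0.38 ± 0.10, as the plasma cell score followed the monocyte score with a slope of 0.31 ± 0.06. The remaining 16 lists were not called, ribosome biogenesis with 2 of 23 higher and 6 lower (adjusted p 0.404) among them, and the CD8 and gamma-delta T cell list had a median of 0.20 but a mean of -0.19. The unfolded protein response was called without array N4 (median 0.23, adjusted p 0.0333) or G6 (0.23, 0.0352), and neutrophil markers without B3 (0.89, 0.0267). With undetected genes at their bounds, the median of interferon-stimulated genes was 3.35 and that of neutrophil markers 0.23 instead of 0.89.

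**Figure D3:**
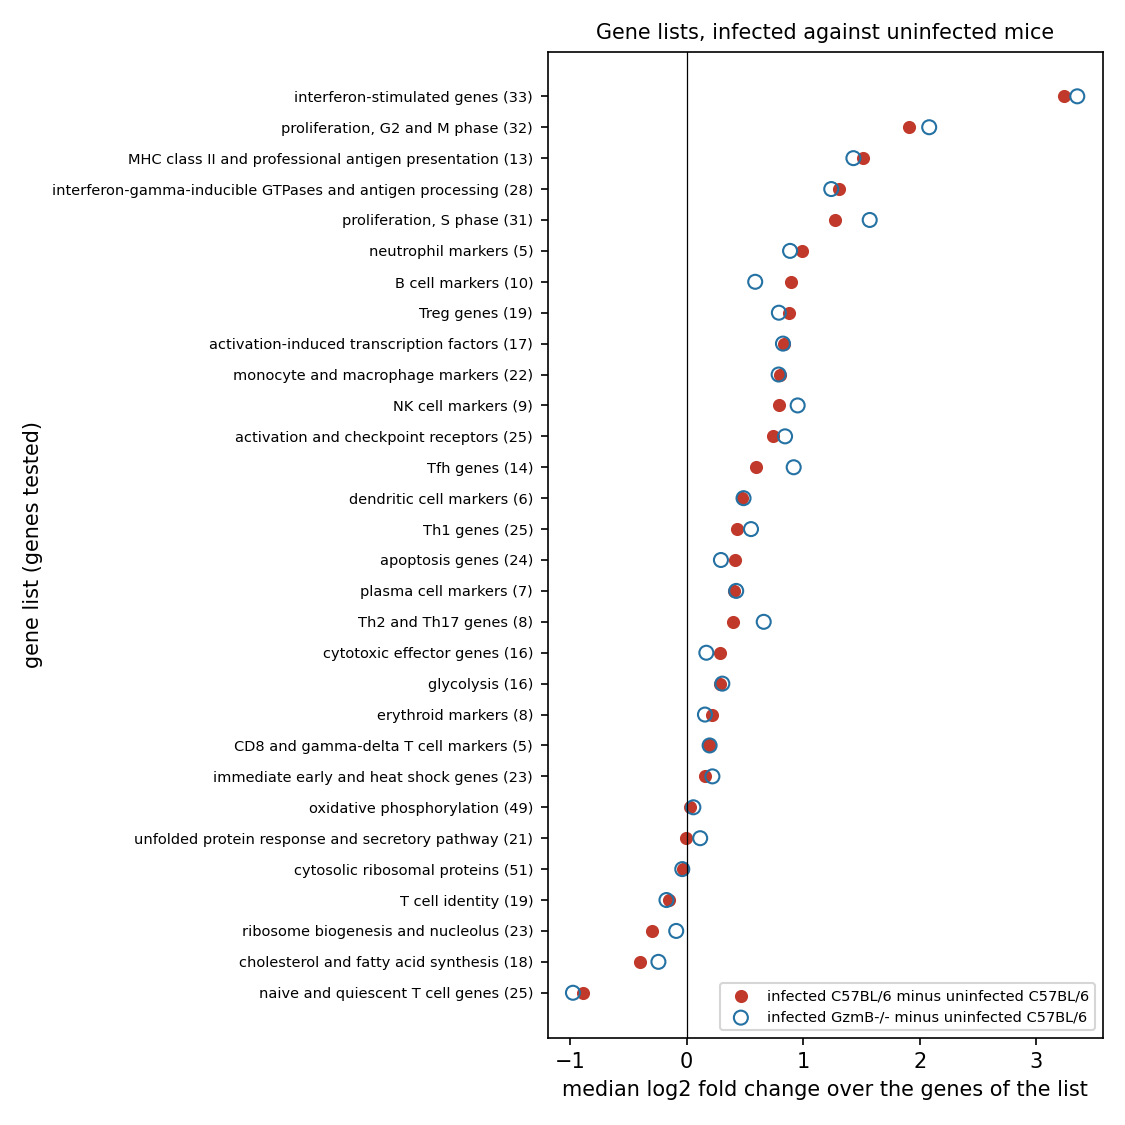
Median log2 fold change of each gene list, with the number of genes tested in brackets, for infected C57BL/6 (filled points) and infected GzmB-/- mice (open circles) against uninfected C57BL/6 mice. Interferon-stimulated genes lie at 3.24 and 3.35 and naive genes at -0.89 and -0.98, and near 0 the ribosomal protein list turns to 0.19 and 0.16 in the deposited value table.

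Both responses share the uninfected arrays. Of the genes called, 1268 were higher in both comparisons and 1505 lower in both, where independent lists would share 271 and 413, and 3 went opposite ways. Across genes, which are not independent replicates, the fold changes correlated at 0.9393, against 0.499 in simulations of unchanged groups against the same controls, and at 0.8809 to 0.911 with the controls split between the comparisons. The covariance was 0.498 against 0.0177 in the simulations, a difference of 0.4803.

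Between the infected genotypes few genes differed, and most of those that did lie on the chromosome of Gzmb. Of 9018 genes 17 (0.189%) passed limma's adjusted threshold, 5 higher and 12 lower in GzmB-/- mice (n = 4 per group), and 12 of the 17 lie on chromosome 14. Supt16 was lower by -4.18 ± 0.17 on its brightest probe, Sall2, a zinc finger gene, by -1.98 ± 0.21, and Psmb5, a proteasome subunit gene, by -1.06 ± 0.11. Rnase4, a secreted ribonuclease gene, was higher by 2.42 ± 0.14. Ifng (-0.04, 95% interval -0.60 to 0.52), Ifit3 (0.20, -0.14 to 0.54) and Mcm10 (0.28, -0.38 to 0.94) did not pass.

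The other chromosome 14 genes, all lower, were Dlgap5 (-1.86 ± 0.24), Ndrg2 (-1.63 ± 0.14), Tmem254a (-1.56 ± 0.14), Bcl2l2, a BCL2-family survival gene (at least 2.33-fold, its probe being undetected in GzmB-/- mice), Tmem260 (-1.30 ± 0.11), Fbxo34 (-0.73 ± 0.10), Gch1 (-0.65 ± 0.11) and Glud1 (-0.62 ± 0.10). Tmem254a has near-identical copies, which its probe may not keep apart. Off chromosome 14, Thg1l on chromosome 11 (1.44 ± 0.20), Sppl2a on 2 (1.05 ± 0.19), Cd28 on 1 (0.94 ± 0.16) and Exoc4 on 6 (0.78 ± 0.13) were higher, and Rara, the retinoic acid receptor alpha gene on 11, was lower (-0.999 ± 0.17). Chromosome 14 holds 299 of the tested genes (3.32%), so 0.564 of 17 would fall there by chance, with a two-sided Fisher's exact p of 7.58e-15. All 12 lie on 1 side of Gzmb in gene order, the side with 171 tested genes, at most 121 tested genes away. The 26 tested genes nearest to Gzmb on that side hold 0 of them, and the 50 nearest on each side hold 5, where an even spread over the chromosome would give 4.01. All but Glud1 (84) and Tmem254a (121) lie between 27 (Bcl2l2) and 70 (Gch1) tested genes from Gzmb.

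**Figure D4:**
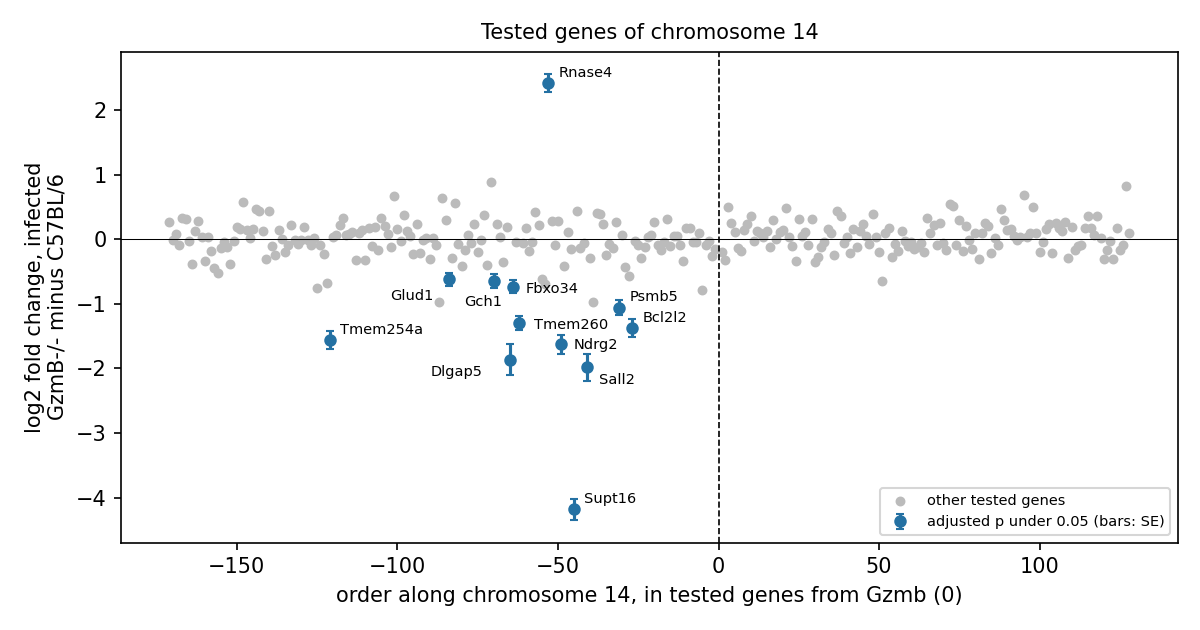
Log2 fold change (infected GzmB-/- minus infected C57BL/6) of the 299 tested genes of chromosome 14 against their order along it, counted in tested genes from Gzmb at 0. Blue points with standard error bars mark the 12 called genes, all on the low side and up to 121 tested genes away, and grey points the others, with Bcl2l2 drawn at its fitted value although its probe was undetected in GzmB-/- mice.

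For Dlgap5, Ndrg2 and Supt16, no further probe followed the brightest one, and the second Supt16 probe read higher, at 0.60 ± 0.11 (unadjusted limma p 0.000144). In Bcl2l2, Fbxo34 and Tmem260 at least 1 further probe moved alike, but another probe of Bcl2l2 (0.18) and of Fbxo34 (0.21 ± 0.07, unadjusted limma p 0.00684) did not. The further probes of Glud1 past the detection filter read 0.26 and -0.19, that of Gch1 -0.43 and those of Exoc4 -0.02 and 0.32, and the mean of the probes of a gene gave -0.18 (adjusted p 0.76), -0.54 (0.252) and 0.36 (0.358) for these 3, without a call. The call of 11 genes, 10 of them on chromosome 14 and Thg1l, held in all 12 fits that left out 1 array. Under the other alternatives Thg1l lost it in 3 of 13 (adjusted p 0.00414 to 0.0617), Dlgap5 in 2 of 13 (0.00109 to 0.152) and Fbxo34 in 3 of 14 (0.00198 to 0.121), and with only the 8 arrays compared the 8 genes called all lie on chromosome 14. The call of Cd28 held only without array B5 (elsewhere adjusted p 0.067 to 0.129), that of Gch1 only without G6 (0.0546 to 0.14) and that of Sppl2a only without N4 or G1 (0.0619 to 0.163). Rara lost it without N1, N3, B3, B4, B5, B6, G3, G4 or G6 (0.0718 to 0.144), Glud1 without N1, N3, B3, B5, B6, G3, G4 or G6 (0.0533 to 0.0939) and Exoc4 without N2, N3, B3, B5, G3, G4 or G6 (0.0566 to 0.115). Under the other alternatives Cd28 lost it in 6 of 14 (0.00571 to 0.249), Gch1 in 5 of 14 (0.00369 to 0.252), Glud1 in 4 of 14 (0.004 to 0.76), Exoc4 in 3 of 14 (0.00917 to 0.358), Sppl2a in 7 of 14 (0.0148 to 0.197) and Rara in 11 of 13 (0.0301 to 0.184). The number of genes called was 11 without array N3.

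No member of any interferon, proliferation, helper or naive list passed, although camera called 4 lists higher in GzmB-/- mice with small medians. S phase genes had a median of 0.16 (adjusted p 0.0124), G2 and M phase genes 0.21 (0.0185), ribosome biogenesis 0.12 (0.0185) and cholesterol and fatty acid synthesis 0.19 (0.0185). Each gave adjusted p = 0.853 with an estimated correlation, and 0 of their members were called adjusted over the list alone. Among lists that camera did not call, 1 regulatory T cell gene and 1 activation-induced transcription factor were lower adjusted over the list alone, and 1 T cell identity gene was higher. The S phase call ended without array B4 (adjusted p 0.138), B6 (0.31) or G4 (0.186), that of G2 and M phase without B4 (0.348), B6 (0.544), G1 (0.0754) or G4 (0.224), that of ribosome biogenesis without B4 (0.138), B5 (0.129) or G4 (0.186), and that of cholesterol synthesis without B4 (0.0837), B5 (0.0802), G1 (0.158) or G4 (0.186). The medians of S phase and G2 and M phase genes rose to 0.27 and 0.45 without B5 and to 0.26 and 0.38 without G6, and that of cholesterol synthesis to 0.32 without B6 and 0.38 without G6. The number of lists called was 0 without array G4, 1 without B4, 2 without B5, B6 or G1, and 9 without B3. Without B3 the further calls, all higher in GzmB-/- mice, were monocyte and macrophage markers (median 0.54, adjusted p 0.000285, where all arrays gave 0.11), Th1 (0.14, 0.0216), follicular helper (0.18, 0.0148), MHC class II (0.28, 0.0487) and neutrophil genes (0.48, 0.0454). Follicular helper genes were also called without G3 (0.20, 0.0147), the unfolded protein response without G6 (0.12, 0.0427) and B cell markers, lower, without B4 (-0.47, 0.0323) and with the monocyte score as covariate (-0.38, 0.0165). With all arrays the remaining 26 lists were not called, interferon-stimulated genes lying at a median of 0.02 (adjusted p 0.385), and the T cell identity list held 1 called gene, Cd28. Median, mean and test differed in sign for the naive, activation-induced transcription factor, apoptosis, immediate early, MHC class II, dendritic cell and erythroid lists. Fry called 0 lists with members moving 1 way, and 3 with members moving either way: T cell identity (adjusted p 0.0257), immediate early and heat shock (0.0352) and regulatory T cell genes (0.0455). At an unadjusted p under 0.05 limma gave 1050 genes where chance would give 451, and the groups did not overlap for 509 genes (5.64%, against 2.86% by chance). That a gene passed in 1 infection response and not in the other does not show a difference between genotypes, which this comparison alone tested.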

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

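The counts of other splits of the samples were planned before the results were seen, and the tests of strain DNA, batch, other cells, single probes and covariates were chosen after. In infected GzmB-/- mice against infected C57BL/6 mice, 17 genes differed by limma's test of the difference. On the log2 scale Supt16 differed by -4.185, Sall2 by -1.98, Dlgap5 by -1.865, Ndrg2 by -1.629, Tmem254a by -1.558, Tmem260 by -1.297, Psmb5 by -1.061, Fbxo34 by -0.7349, Gch1 by -0.6491, Glud1 by -0.6206 and Rnase4 by 2.416, while Bcl2l2 was at least 2.33-fold lower, its probe being undetected in GzmB-/- mice, all on chromosome 14. Off it, Thg1l differed by 1.436, Sppl2a by 1.055, Cd28 by 0.9356, Exoc4 by 0.7776 and Rara by -0.9988. Of the 35 splits of these 8 arrays, 1, the real one, called as many genes (17, highest other 1), which is the smallest share that 35 splits can give. Camera called 4 lists, with medians of 0.161 for S phase, 0.212 for G2 and M phase, 0.123 for ribosome biogenesis and 0.193 for cholesterol and fatty acid synthesis. With an estimated correlation 0 of them were called (camera adjusted p 0.853 each), and 0 of their members passed. For lists, 19 of the 35 splits called 4 or more (highest other 14), so chance is not excluded. A structure of the arrays other than genotype, or genes moving together within lists, may give such counts, and no test separated them.

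For the genes on chromosome 14, DNA of another strain kept on the chromosome of the inactivated gene may be the source, since 12 of 17 lie there with a two-sided Fisher's exact p of 7.58e-15. All 12 lie on 1 side of that gene, and all but Glud1 and Tmem254a lie 27 to 70 tested genes from it. However, 0 of the 26 nearest tested genes on that side and 0 of the 128 on the other side were called, so the called genes do not surround it. The position of called genes along chromosome 14 was not tested. A batch or quality difference between the groups would place 0.564 genes there by the share of tested genes, which argues against it for this part. With the monocyte and macrophage marker score as a covariate, 11 of the chromosome's genes passed. That score differed little between the infected genotypes (mean 0.129), so the covariate could hardly move these differences whatever their source. The fit therefore cannot decide whether monocytes and macrophages had a part. A sequence variant under only 1 probe is argued against for Tmem260, where 3 probes fell. Without probe positions, a variant shared by these probes, or several variants, is not excluded for it. For the others a variant cannot be told apart from changed transcript levels: for 3 of 8 genes with a further probe none followed, and 8 genes had 1 probe, under 3 that moved alike or undecided ones, without probe positions or strain sequences to decide. In Supt16 and Fbxo34 a further probe detected on 12 arrays read higher (0.60 ± 0.11 and 0.21 ± 0.07), opposite to the brightest probe, so a fall of the whole transcript is not shown for them. An effect of lost granzyme B on the chromosome 14 genes stays open and was not tested, as the design has no uninfected GzmB-/- mice and no littermates with the same flanking DNA.

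For the markers of other cells that rose with infection, monocytes and neutrophils or their RNA in the sorted samples may be the source, although the flow sorting would remove most such cells. Over the 8 infected arrays, centred within genotype, monocyte and neutrophil scores correlated at r = 0.938 (exact permutation p 0.00174, the smallest that 576 arrangements give, adjusted 0.00348 over 4 relations; rho 0.905, p 0.00347), and at 0.833 without B3 and B4, while B cell markers gave r = 0.914 (p 0.00868, adjusted 0.0116, 0.543 without B3 and B4), MHC class II genes 0.969 (0.00174, adjusted 0.00348, 0.874) and T cell identity -0.599 (0.375, adjusted 0.375, -0.0835), so a fall of T cell transcripts with them was not shown. Such cells are argued against as the whole cause of 4 list changes in infected C57BL/6 mice, since with the monocyte score as covariate the list score of interferon-stimulated genes was 3 ± 0.0828 (2.96 before), S phase 1.29 ± 0.179 (1.45), Th1 0.657 ± 0.102 (0.776) and Treg 1 ± 0.115 (0.951). Of the named genes called in infected C57BL/6 mice, 11 of 125 lost the call with this covariate. For MHC class II genes the list score was 0.83 ± 0.113 (1.35 before), with a slope of 0.615 ± 0.0727 on the monocyte score. Part of the rise thus followed the monocyte score, and for the rest T cells and other cells cannot be told apart. S100a8 ran from 4.732 to 5.705 in uninfected and from 7.786 to 11.98 in infected C57BL/6 arrays, and infection itself as the cause in T cells stays open.

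For infection in C57BL/6 mice, 1 of 35 splits, the real one, called as many genes (3528, highest other 2), and for infected GzmB-/- against uninfected mice also 1 (3460, highest other 0), the smallest share that 35 splits can give. The other splits mix infected with uninfected arrays, which widens the spread within each side, so few calls were likely in them. For lists, 7 of 35 splits called 13 or more in the first (highest other 18) and 4 of 35 called 14 or more in the second (highest other 19), so these splits do not exclude chance for the number of lists. The other splits that called as many kept 3 arrays of a group together and so held part of the infection difference. Among the 18 splits with 2 arrays of each group on each side, 0 called as many in either comparison (highest 11 and 4).

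In 21 of 426 groups of 4 arrays 1 array stood far from the others, where chance gives 21.3. In uninfected mice, array N1 read 10.63 for Cd274 (others 10.75 to 10.78), 9.906 for Ampd3 (9.62 to 9.656) and 6.883 for Tyrobp (6.133 to 6.21). Array N2 read 10.2 for Lag3 (8.456 to 8.659), 7.83 for Gzmk (5.613 to 5.874) and 9.23 for the mean of activation-induced transcription factors (9.035 to 9.058). Array N3 read 12.22 for Il6ra (11.8 to 11.84). Array N4 read 7.496 for Sall2 (8.133 to 8.153), 12.66 for Glud1 (12.83 to 12.85), 9.009 for Sppl2a (8.25 to 8.255) and 9.685 for the mean of the unfolded protein response (9.45 to 9.488). In infected C57BL/6 mice, array B3 read 11.94 for Ifi27 (11.42 to 11.5), 11.98 for S100a8 (7.786 to 8.198) and 10.69 for Cd79b (8.336 to 8.699). Array B4 read 13.81 for Socs3 (13.55 to 13.59) and 10.49 for the mean of cytotoxic genes (10.65 to 10.68), and B6 read 9.33 for Polr1b (9.032 to 9.052) and 14.55 for the mean of cytosolic ribosomal proteins (14.46 to 14.47). In infected GzmB-/- mice, array G1 read 11.2 for Mpeg1 (11.47 to 11.51), and G3 read 10.03 for Mx2 (10.41 to 10.49) and 11.09 for Klf6 (12.32 to 12.45).

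Of 2675 probes above background without a single gene name, 695 changed with infection in C57BL/6 mice, 288 higher and 407 lower, and 664 and 15 differed in the other comparisons. Between the infected genotypes 11 of the 15 were higher and 4 lower in GzmB-/- mice, with log2 differences up to 3.04 and down to -3.17. These probes were not placed on a chromosome, so the count of called genes on chromosome 14 does not cover them.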

How the results depend on the processing

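Leaving out arrays B3 and G3, the replicate block and the monocyte covariate were alternatives chosen after seeing the data. Outside leave-one-out, named genes kept direction and call in 1677 of 1711 values for infection in C57BL/6, 1898 of 1957 for infected GzmB-/- against uninfected mice and 189 of 233 between infected genotypes, and the others, 34, 59 and 44, only lost the call. For lists, a call or its absence was kept in 394, 390 and 399 of 415 values. A list called in neither setting counts as kept there even where its direction turned. Between genotypes only 4 of 30 lists were called to begin with, so 399 mostly counts lists that stayed uncalled. For named genes in both comparisons with uninfected mice, the monocyte covariate ended more calls than any other setting, 11 of 125 and 18 of 143. The direction of cytosolic ribosomal proteins reversed in infected GzmB-/- mice under median scaling (0.0815) and, in both responses, in the deposited value table (0.187 and 0.163), with the replicate block too (0.187 and 0.163), and the cause was not tested. Genes between genotypes were 11 with median scaling, and the cause was not tested, 8 with only 8 arrays, which leaves fewer samples, and 11 at 2-fold or more, where the comparisons with uninfected C57BL/6 mice gave 914 and 898, by the stricter threshold. Lists between genotypes were 2 with the mean of probes and 7 without B3 and G3, and the cause was not tested. With an estimated correlation 2, 5 and 0 lists were called, as that test allows for genes moving together, and with fry 23, 22 and 0, as fry does not compare a list with other genes. The correlation of the responses was 0.949 in the value table, with and without the block, 0.924 without a filter and 0.925 without B3 and G3, and the cause was not tested.

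Leaving out 1 array at a time, infection in C57BL/6 mice changed 3025 (N4) to 3656 (G3) genes, with 11 (N3) to 14 (B4) lists. Infected GzmB-/- against uninfected C57BL/6 mice, where genotype and infection enter together, gave 2958 (N1) to 3615 (B3) genes and 12 (N2) to 15 (N4) lists. Between genotypes, leaving out 1 array gave 11 (N3) to 18 (B6) genes, 10 to 11 of them on chromosome 14, and 0 (G4) to 9 (B3) lists. The correlation of responses ran from 0.923 (B3) to 0.942 (B4) and the Gzmb difference from -0.0997 (G1) to 0.00693 (G6). Without B3 the direction of the test between genotypes reversed for MHC class II genes, with a median of 0.275 (lowest -0.243, without B4), and neutrophil markers, with 0.475 (lowest -0.443, without B6), and the cause was not tested. Replicate numbers gave no clear pairing of the mice: of 12 same-number pairs 4 correlated above 0.1, from -0.236 to 0.509, and 3 were best with their own number. This does not exclude that mice of 1 number were handled together. With them as a block on the value table the counts were 3853, 3869 and 13, and 3841, 3845 and 20 without it. Of the genes called between genotypes, the block ended the calls of Thg1l and Cd28 (adjusted p 0.0509 each) and Sppl2a (0.0981), while that of Rara had ended in the value table without it (0.119). Without background correction the changes of called genes were smaller, with a median ratio of 0.851, 0.852 and 0.767 on the log2 scale, and the bounds given as folds, other than that of Tubb1 (1.19-fold without it), are then not reached: S100a8 was 5.34-fold and 4.87-fold higher and Cxcl9 7.9-fold in infected GzmB-/- mice. Signal over background limits dim genes such as Gzmb.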

Other observations

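The families and genes here were chosen after their values were seen, and no test was run on them beyond the limma fit. Suppressors of cytokine signalling, which restrain JAK-STAT signalling, rose in part with infection: in C57BL/6 mice 4 of 7 tested members were higher and 0 lower (1 lower with median scaling and in the deposited value table), with Socs3 at 2.64 ± 0.14 and Socs1 at 2.01 ± 0.20 (n = 4 per group). In infected GzmB-/- mice 4 were higher and 1 lower (3 and 1 with median scaling). Metallothioneins, which bind zinc and copper, were higher in 2 of 3 cases in both responses under each scaling, Mt1 at 3.29 ± 0.30 in C57BL/6 and 3.35 ± 0.30 in GzmB-/- mice (2.20 and 2.24 without background correction), and Mt3 at least 6.28-fold and 4.04-fold higher (4.21-fold and 3.11-fold without background correction). Of the Fc gamma receptors, which bind antibody, 3 of 4 were higher in both responses under each scaling, Fcgr4 by 3.89 ± 0.48 and 4.33 ± 0.48. Fcgr4 is a gene of myeloid cells, and S100a8, a neutrophil gene, was higher in the same arrays.

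Kallikrein genes of the Klk1 family were higher in 5 of 5 cases in infected C57BL/6 mice (4 with median scaling) and 3 of 5 in GzmB-/- mice, Klk1 by 3.33 ± 0.54 and 2.99 ± 0.54, with members so alike in sequence that a probe's gene is uncertain. AMP deaminases, enzymes of purine turnover, were lower in 2 of 3 cases in C57BL/6 and 3 of 3 in GzmB-/- mice (2 without background correction), with Ampd3 at -1.85 ± 0.12 and -1.92 ± 0.12. Of 9 Krüppel-like factors 5 were lower in C57BL/6 (6 with median scaling) and 2 in GzmB-/- mice (5 with median scaling and in the value table), with Klf2, a factor of T cell quiescence and trafficking, at -0.98 ± 0.16 and -1.28 ± 0.16. Mlkl, the effector gene of necroptosis, was at least 10.1-fold higher in both responses, and Cdkn1a, a cell cycle inhibitor gene, was at least 8.1-fold and 8.38-fold higher (4.66-fold and 4.74-fold without background correction) beside the proliferation genes, with probes from 0.96 to 3.81 in C57BL/6 mice.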
